A study of Rattus norvegicus with 10 samples.

How the data were processed

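Left ventricular RNA of male Sprague-Dawley rats was measured on Affymetrix rat whole-genome expression arrays 3 days after gene transfer. The labels place 5 samples in a group that received the gene for GATA-4 and 5 in a group that received LacZ, the bacterial beta-galactosidase gene used as a control. Groups were taken from the source label of each sample, since the sample titles name GATA-4 on all 10 arrays, LacZ ones included, and do not separate the groups. The labels give no replicate numbers shared between the groups, so numbers 1 to 5 only name the arrays. Per the labels' protocols, total RNA was isolated with guanidine thiocyanate and caesium chloride, the target carried biotin, and arrays were stained with streptavidin-phycoerythrin with an antibody amplification step. The delivery vehicle and the injection site are not given in the sources used here.

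The values are probe set intensities on a linear scale, deposited by the authors as a table of 10 columns and made with GCOS, Affymetrix's array software, per the submitters' processing notes. The GCOS version, the summary algorithm and any scaling to a common level are not given in the sources used here. The table held 31042 probe sets and 57 array control probe sets. No detection calls were used. Probe sets were named through GEO's platform annotation, with symbols updated by gene ID from a RefSeq gene table of assembly GRCr8. Gene IDs of 20764 of the 21268 annotated probe sets matched. A single gene was listed for 20826 probe sets, several genes for 436 and none for 9780, and no gene was named from a probe set with several or none. Genome coordinates were not used.

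Values were taken to log2. The 2%-trimmed mean signals of the 10 arrays lay more than 5% apart, so the log2 values were quantile normalized over the probe sets that are not controls, as a rule fixed in advance required. The normalized values were then floored at a log2 of 0, that is an intensity of 1. A probe set was tested where its mean log2 value over the 10 arrays lay above the 40th percentile, which left 18625 probe sets. Each was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), with no covariates. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the probe sets tested, with a threshold of 0.05. All adjusted p-values of single genes come from this limma fit. The words rose, fell and changed are kept for genes past that threshold. A second, exploratory count took probe sets with an unadjusted p under 0.01 and a fold of at least 1.5. Single measures such as the 3' to 5' ratios were compared with exact two-sided permutation tests over the 252 assignments of 5 and 5 arrays, for which 0.00794 is the smallest p possible.

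For gene-level results, the probe set with the highest mean log2 value stood for its gene, which gave 10688 genes. The 31 gene lists, with 891 entries of which 774 were matched on the array, were fixed before the data were examined. They cover cardiac transcription factors, GATA-4 targets and hypertrophy genes, angiogenesis, paracrine factors, interferon response, antigen presentation, inflammation, matrix, cell cycle, apoptosis, stress, ribosomal proteins, energy metabolism, ion handling, and markers of cell types that a piece of ventricle can hold. Lists were tested against all other genes with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the 31 lists. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way, were run beside it. A list score is the mean over its genes of each array's log2 deviation from the gene's mean over the 10 arrays.

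Genes are named by a rule fixed beforehand. It takes Gata4, the 10 largest rises and 10 largest falls among changed genes whose groups did not overlap, the 4 members with the smallest unadjusted p of each list past camera's threshold, and the changed member with the smallest p of each other list. Names outside this rule were chosen after their values were seen, and the text says so.

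The alternatives were the values as deposited, centring on the median, another added constant, another floor, no filter, a stricter filter, limma without the trend, robust limma, array weights, and leaving out each array in turn. A pair of further settings, without GATA-4 arrays 4 and 5 and with median centring without GATA-4 array 1, was added after seeing the data, the first because these arrays' sample numbers lie apart from the others'. In simulated data on the same 18625 probe sets, with 200 changed, the limma fit recovered 6% of those changed 1.25-fold, 28% at 1.5-fold, 82% at 2-fold and 92% at 3-fold, and 5 of its 109 calls were false. The simulated noise was normal and independent between probe sets, and no array was outlying. These shares therefore need not hold for the real arrays, where genes vary together and 1 array lies apart. Array weights used statmod 1.5.0. The arrays' number limits the precision.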

Results

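Gene expression in the left ventricle was measured in 10 rat samples taken on day 3, 5 after GATA-4 gene transfer and 5 after LacZ gene transfer. GATA-4 is a zinc finger transcription factor of heart muscle and other tissues. The design text names 5 animals in each group, as many as there are samples, while the sample labels do not name an animal. The p-values of limma and of the exact tests measure the spread between these samples. Those of camera at its preset correlation of 0.01 do not, since that setting treats the genes of a list as nearly independent. GATA-4 arrays 4 and 5 carry sample numbers apart from the run that holds the other 8 arrays, and no batch is labelled. With the 8 arrays of that run alone 201 probe sets changed, 139 higher and 62 lower, where all arrays gave 988, and the fewer arrays and a batch cannot be told apart. The 2%-trimmed mean signal ran from 250.2 to 315 on the LacZ arrays and from 251 to 329.9 on GATA-4 arrays 2 to 5, and was 143 on GATA-4 array 1, called the dim array here. Its spiked hybridisation controls, at a mean log2 of 9.35, lay within the 9.20 to 9.50 of the other arrays, while its poly-A spikes, at 6.47, lay below their 7.30 to 8.44. The log2 3' to 5' ratio of the GAPDH and beta-actin controls was 1.07 ± 0.17 with GATA-4 and 1.08 ± 0.25 with LacZ (SD, n = 5), an exact two-sided permutation p of 0.984. Against the middle instead of the 5' probe sets the groups differed by -0.194, with an exact p of 0.0476.

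The transferred gene was read first, as a check of the labels. Gata4, by its brighter probe set, had a normalized log2 signal of 11.44 ± 0.14 on the GATA-4 arrays and 10.65 ± 0.13 on the LacZ arrays (SD, n = 5 each; exact permutation p = 0.00794, the smallest possible). The rise of 0.79 (SE 0.09), or 1.73-fold, passed limma with an adjusted p of 0.00131. All 5 GATA-4 arrays, the dim array with 11.58 among them, lay above all 5 LacZ arrays. A second Gata4 probe set was too dim to pass the filter and read 5.24 ± 0.65 against 4.44 ± 1.11 (SD, n = 5), an exact permutation p of 0.190. Whether these probe sets read the transferred sequence, the rat's own transcript or both was not tested. With the signals as deposited, without normalization between arrays, the Gata4 difference was 0.70 and limma's adjusted p was 0.993, the highest among the alternatives, whose lowest was 1.03e-04.

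**Figure D1:**
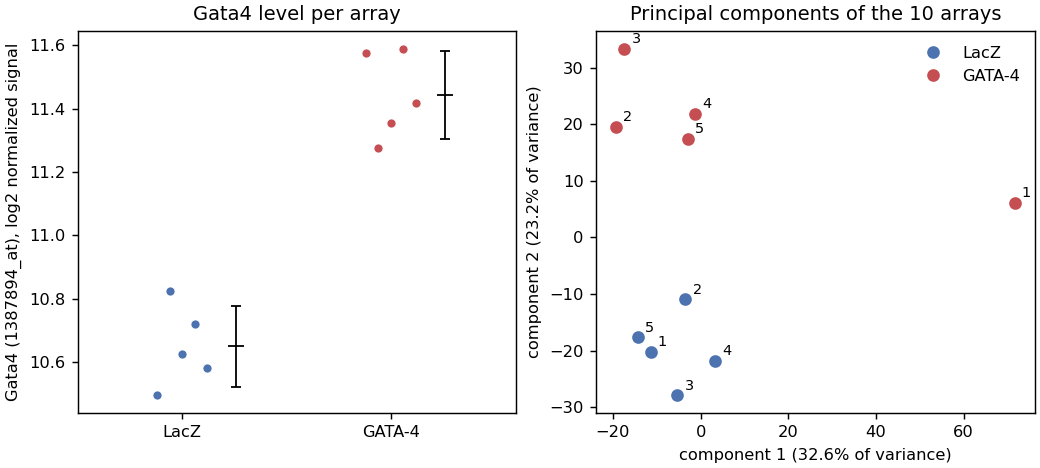
The left panel plots the normalized log2 signal of Gata4 per array in each group, with bars for the mean ± SD, and the right panel plots the arrays on their first principal components, with 32.6% and 23.2% of the variance, numbered by replicate. The GATA-4 arrays lie above the LacZ arrays in Gata4, the dim array stands alone at 71.6 on component 1, and the groups separate on component 2.

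The comparison of GATA-4 with LacZ asked which ventricular transcripts differ after the transfer. The genes with the largest rises were Reg1a (16.7-fold, adjusted p = 0.00455) and Reg3g (13.5-fold, adjusted p = 0.0062 in limma), secreted lectins of the regenerating family, and Krt18, a keratin of simple epithelia (13.4-fold over a LacZ signal near background, adjusted p = 0.00714). Some members of the lists of interferon response (12 of 33), antigen presentation (8 of 21), inflammation (7 of 38), macrophages (12 of 32), cell division (11 of 37) and matrix (6 of 38) rose, Timp1 and Tnc among them. Some of fatty acid oxidation (6 of 30), the respiratory chain (5 of 43) and calcium handling (3 of 29) fell, such as Etfb by 0.30 and Casq2 by 0.31 on the log2 scale. Camera passed these 9 lists at its preset correlation, and for each the adjusted p was 0.28 with an estimated correlation. Of 10688 genes tested 397 rose and 284 fell, and 55 of the rises but 2 of the falls exceeded 2-fold.

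Over probe sets, limma called 988 of 18625 changed, 566 higher and 422 lower with GATA-4, and 4105 had an unadjusted p under 0.05. Under centring on the median the split was 468 higher and 608 lower. Groups did not overlap in 1032 genes, 573 of them changed, where chance gives 0.794% or 84.8 genes. A looser, exploratory count held 575 probe sets at an unadjusted p under 0.01 and a fold of at least 1.5, where 186.25 are expected below that p alone. The count of changed probe sets rested on single arrays: it was 2849 without the dim array, 174 without LacZ array 3, 384, 391 and 323 without LacZ arrays 1, 4 and 5, 341, 558 and 539 without GATA-4 arrays 3, 4 and 5, and 9 in the signals as deposited. No gene was listed alone for 181 of the changed probe sets, which are counted and not named.

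Below the Reg genes and Krt18, the largest rises were those of Gal (7.83-fold), the neuropeptide galanin, and Tgm1 (5.98-fold), a protein-crosslinking transglutaminase, with limma adjusted p-values of 0.00198 and 0.00074. Aldoc, an aldolase of glycolysis, rose 4.52-fold, Sh3bp1 4.42-fold, Testin 3.86-fold, Gtse1, a protein of dividing cells, 3.29-fold and Uchl1, a ubiquitin hydrolase, 3.11-fold. Krt18, Gal, Sh3bp1, Gtse1, Uchl1, Testin and Tgm1 were dim with LacZ, at log2 signals of 3.54, 3.88, 4.17, 4.51, 4.51, 4.71 and 4.78, so their folds and their order are approximate. With 16 added to every signal their log2 differences were 2.51, 2.07, 1.49, 1.24, 1.15, 1.48 and 2.05 instead of 3.74, 2.97, 2.14, 1.72, 1.64, 1.95 and 2.58, and with a floor at the 20th percentile that of Krt18 was 3.21. Reg1a stood at 9.74 ± 1.23 against 5.68 ± 0.92 in log2 signal and Krt18 at 7.28 ± 0.74 against 3.54 ± 1.44 (SD, n = 5), so that spread within groups was wide for both. On the dim array Reg1a read 9.54 and Krt18 7.54, each above all LacZ arrays. Uchl1 missed the threshold in 3 of the 10 fits that left out an array.

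Falls were smaller. Pdzk1, a scaffold protein with PDZ domains, fell 2.46-fold (limma adjusted p = 0.0151) and C20h22orf15 2.04-fold (adjusted p = 0.0482). Both were dim with GATA-4, at log2 signals of 4.92 and 5.39, so these folds are approximate, and with 16 added to every signal the log2 differences were -0.95 and -0.79 instead of -1.30 and -1.03, each under 2-fold. Hs3st5, a heparan sulfate sulfotransferase, fell 1.87-fold, Ppp1r3a, a glycogen-targeting phosphatase subunit, 1.80-fold, Sctr, the secretin receptor, 1.79-fold, and Fgf12 1.70-fold. Ift70b, Apln, Omd and Kcnk2 fell by 1.69-fold or 1.68-fold. Hs3st5 and Apln each had 1 other tested probe set, which differed in the same direction and did not pass. Apln encodes the peptide apelin, Omd a small matrix proteoglycan and Kcnk2 a potassium channel, and their adjusted p-values in limma ran from 0.00645 to 0.0174. C20h22orf15 missed the threshold in 9 of the 10 fits that left out an array, Ppp1r3a in 8 and Hs3st5 in 6.

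**Figure D2:**
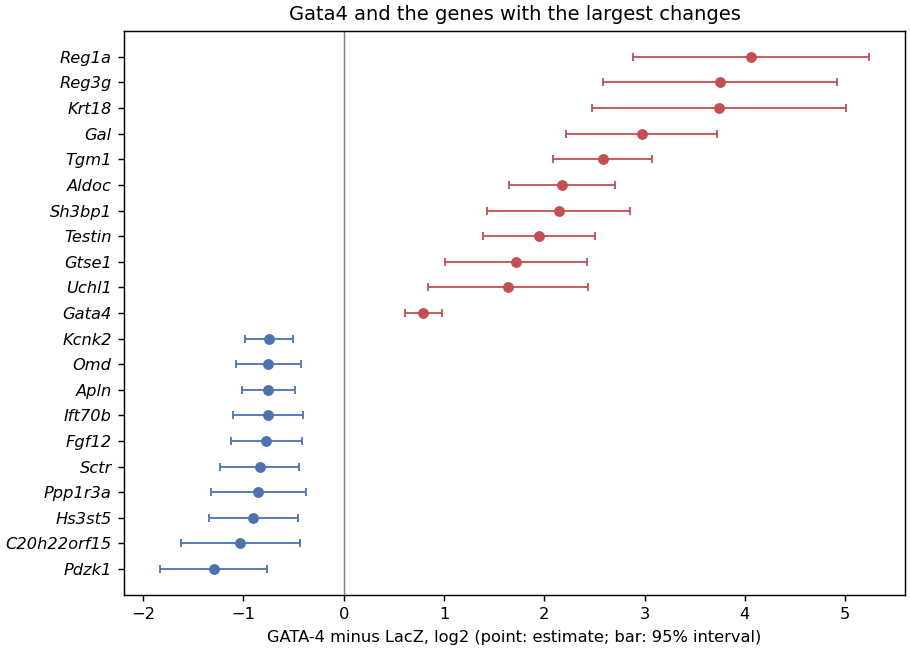
Points give the log2 difference between GATA-4 and LacZ arrays for Gata4 and for the 10 largest rises and 10 largest falls, and bars its 95% interval in limma. Reg1a leads at 4.06 and Pdzk1 lies lowest at -1.30.

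All 33 measured interferon-response genes had positive differences, 12 rose and none fell, with a median of 0.60 on the log2 scale. Oas1a, an antiviral oligoadenylate synthetase, rose 2.18-fold, Lgals3bp 2.05-fold, Ifi27l2b 2.03-fold and Mx1, an antiviral GTPase, 1.87-fold, with limma adjusted p-values from 0.00418 to 0.00714. Camera gave the list an adjusted p of 2.64e-15, fry 0.0321, and the adjusted p was 0.28 with an estimated correlation. Adjusted over the list alone, 23 members rose. The dim array had a list score of -0.16, within the -0.53 to -0.15 of the LacZ arrays, against 0.19 to 0.79 on the other GATA-4 arrays. Without it 28 members rose. Leaving out a GATA-4 array that scores near the LacZ arrays tends to raise such a count of itself. Counts without the dim array, here and for the lists below, therefore add no support.

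Antigen presentation genes went the same way in all 21 measured members, of which 8 rose and none fell (median 0.41). RT1-DMa, which loads class II molecules with peptide, rose 1.67-fold, the immunoproteasome subunits Psmb8 and Psmb9 1.58-fold and 1.53-fold, and Tapbp, which serves class I loading, 1.46-fold, with limma adjusted p-values from 0.00645 to 0.0248, and Psmb9 missed the threshold in 5 of the 10 fits that left out an array. Camera's adjusted p was 1.32e-10 and fry's 0.0135, and the adjusted p was 0.28 with an estimated correlation. With p adjusted over the list alone 14 rose. The score was 0.019 on the dim array and 0.16 to 0.36 on the other GATA-4 arrays, and 16 members rose without the dim array.

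Of 38 inflammation and chemokine genes 7 rose and none fell, with a median of 0.65. Lcn2, an iron-trapping lipocalin, rose 2.49-fold, the cytokine Il1b 1.92-fold, the chemokine Ccl3 1.91-fold and the endotoxin coreceptor Cd14 1.82-fold (limma adjusted p from 0.0104 to 0.0265), and Il1b missed the threshold in 7 and Ccl3 in 5 of the 10 fits that left out an array. Il6, picked out after its values were seen, had the widest difference of the list, 2.13 (SE 0.72), and an adjusted p of 0.104 in limma. Camera gave the list an adjusted p of 5.04e-09 and fry 0.0443, and the adjusted p was 0.28 with an estimated correlation. Of the 38 genes 16 rose when adjusted over the list alone. The score of the dim array was -0.47, inside the -0.63 to 0.06 of the LacZ arrays and apart from the 0.39 to 0.66 of the other GATA-4 arrays, and 23 members rose without it.

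Markers of macrophages and monocytes rose in 12 of 32 measured genes and fell in none (median 0.53). Tyrobp, a signalling adaptor of myeloid cells, rose 2.35-fold (limma adjusted p = 0.00074), the lysosomal marker Cd68 1.61-fold and the growth factor receptor Csf1r 1.45-fold, and Cd14 is a member of this list too. Camera's adjusted p was 6.81e-15 and fry's 0.016, and the adjusted p was 0.28 with an estimated correlation. When adjusted over the list alone 24 rose. The dim array scored -0.15, at the upper end of the LacZ arrays, where the other GATA-4 arrays scored 0.19 to 0.51, and 27 members rose without it.

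Of 10 neutrophil markers named on the array, 5 passed the filter on mean signal and were measured. Among those 5, 3 rose: Il1r2, a decoy receptor (2.79-fold), Lcn2, and Csf3r, the granulocyte growth factor receptor (1.94-fold). With single arrays left out, Il1r2 missed the threshold in 7 and Csf3r in 8 of 10 fits. S100a8 read 1.42 higher (SE 0.64) with an adjusted p of 0.212 in limma. The list had a median of 1.32, camera's adjusted p was 3.0e-04 and fry's 0.0443, and the adjusted p was 0.28 with an estimated correlation. Lcn2, Il1r2 and S100a8 are also in the inflammation list. When adjusted over the list alone 3 rose, and 5 rose without the dim array, whose score of -1.04 compares with 0.81 to 1.35 on the other GATA-4 arrays. Of 26 T and NK cell markers only Coro1a, an actin-binding protein of leukocytes, rose (1.67-fold, limma adjusted p = 0.00749), while Il2rg, Gzma and Gzmb had differences of 0.28, 0.72 and 0.75 that did not pass. That list had a median of 0.28, a camera adjusted p of 7.46e-04, 0.0608 with fry and an adjusted p of 0.37 with an estimated correlation. Of the 26 markers 2 rose when adjusted over the list alone. The dim array scored -0.10 on it and the other GATA-4 arrays 0.043 to 0.37, and 5 rose without the dim array. B cell and plasma cell markers (5 measured of 11 named on the array) and mast cell markers (5 measured of 12) had no changed member, with camera adjusted p-values of 0.774 and 0.0944 and medians of -0.11 and -0.49. For B cells the mean of 0.0015 differed in sign from the median, and for mast cells camera passed in the signals as deposited (adjusted p = 0.0413) and without GATA-4 array 2 (0.0488), in a range of 0.0413 to 0.401.

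Cell cycle genes rose in 11 of 37 measured members and fell in none, with a median of 0.51. Cdk1, the kinase of mitotic entry, rose 1.92-fold, Mki67, a marker of dividing cells, 1.73-fold, the kinesin Kif20a 1.61-fold and the topoisomerase Top2a 1.48-fold, with limma adjusted p-values from 0.00661 to 0.0216. Camera's adjusted p was 5.71e-13 and fry's 0.0394, and the adjusted p was 0.28 with an estimated correlation. Of the 37 genes 21 rose when adjusted over the list alone. The dim array scored -0.32, within the -0.42 to -0.12 of the LacZ arrays, and the other GATA-4 arrays 0.21 to 0.56, and 29 members rose without it.

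Extracellular matrix genes rose in 6 of 38 and fell in none (median 0.16, and 0.023 under median centring without the dim array, where camera's adjusted p was 0.0179 in a range of 3.9e-08 to 0.28 over the alternatives). The matricellular protein Tnc rose 2.14-fold, the proteoglycan Vcan 2.07-fold, the metalloproteinase inhibitor Timp1 2.06-fold and fibronectin, Fn1, 1.62-fold (limma adjusted p from 0.00303 to 0.00786). Col1a1 and Col3a1, looked at after the values were seen, differed by 0.26 and 0.060 and did not pass. Camera gave an adjusted p of 1.08e-05 and fry 0.0321, and the adjusted p was 0.28 with an estimated correlation. When adjusted over the list alone 8 rose. Here the dim array, at 0.10, lay within the -0.020 to 0.27 of the other GATA-4 arrays, and 10 members rose without it.

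Among 34 immediate-early and stress genes 6 rose and none fell. Fosl1, a subunit of the AP-1 transcription factor, rose by about 2.13-fold from a dim LacZ signal (log2 difference 1.09, and 0.78 with 16 added), the metallothionein Mt2A 1.75-fold, Ier3 1.68-fold and the small heat shock protein Hspb1 1.21-fold (limma adjusted p from 0.0167 to 0.0329), of which Fosl1 and Ier3 missed the threshold in 8 and Hspb1 in 5 of the 10 fits that left out an array. The median was 0.17, and 0.089 in the signals as deposited, camera's adjusted p 1.5e-04 and fry's 0.0881, and the adjusted p was 0.37 with an estimated correlation. Of the 34 genes 7 rose when adjusted over the list alone. Apoptosis and survival genes rose in 3 of 30: the pro-apoptotic Bid and Bak1 by 1.92-fold each and the cell cycle inhibitor Cdkn1a by 1.46-fold, while Casp1 differed by 0.52 with a limma adjusted p of 0.0745. Cdkn1a missed the threshold in 8 and Bak1 in 7 of those 10 fits. This list had a median of 0.12, a camera adjusted p of 0.0261, 0.109 with fry and an adjusted p of 0.46 with an estimated correlation, and camera no longer called it without GATA-4 array 2 (adjusted p = 0.112) or 3 (adjusted p = 0.0628), in a range of 0.00702 to 0.461 over the alternatives. Of these 30 genes 4 rose when adjusted over the list alone. On the dim array the scores were -0.22 for stress genes and -0.089 for apoptosis genes. Both lay within the LacZ arrays' -0.28 to 0.0046 and -0.13 to -0.045, against 0.12 to 0.36 and 0.024 to 0.26 on the other GATA-4 arrays. Without the dim array 13 stress genes rose, 7 apoptosis genes rose and 1 fell.

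Fatty acid oxidation genes fell in 6 of 30 measured members and rose in none, with a median of -0.18. The electron-transfer flavoprotein genes Etfb and Etfdh fell by 0.30 and by 0.31 on the log2 scale, Slc25a20, the carnitine carrier of mitochondria, fell by 0.29 and the acyl-CoA synthetase Acsl1 fell by 0.26, with limma adjusted p-values from 0.00983 to 0.0374, and Slc25a20 missed the threshold in 9 of the 10 fits that left out an array. Camera's adjusted p was 5.44e-07 and fry's 0.0321, and the adjusted p was 0.28 with an estimated correlation. Oxidative phosphorylation genes fell in 5 of 43 and rose in none (median -0.11). The complex I subunits Ndufs4, Ndufb10 and Ndufv2 fell by 0.49, fell by 0.27 and fell by 0.19, and Sdhd of succinate dehydrogenase fell by 0.18 (limma adjusted p from 0.0167 to 0.0321), of which Sdhd missed it in 8 of those fits and Ndufs4 and Ndufv2 in 6. Camera's adjusted p was 1.29e-08 and fry's 0.0144, and the adjusted p was 0.28 with an estimated correlation. Adjusted over the list alone, 11 oxidation and 17 phosphorylation genes fell, and without the dim array 13 and 15 did. Its scores, 0.056 and 0.035, compare with -0.22 to -0.028 and -0.12 to -0.037 on the other GATA-4 arrays. The LacZ arrays scored 0.0092 to 0.18 and 0.040 to 0.096, so the dim array lay nearer to them on both lists.

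Glycolysis genes went both ways: of 23, the glucose transporter Slc2a1 (1.48-fold), Pgam1 and Pfkp rose, and Eno3, Pdk1 and Pdha1 fell, the last 5 named after their values were seen, and Slc2a1 missed the threshold in 6 of the 10 fits that left out an array. The list's median was -0.016, its mean 0.020 and camera's adjusted p 0.774, with 5 higher and 7 lower when adjusted over the list alone. Without the dim array too, 5 glycolysis genes rose and 7 fell. Calcium handling and ion channel genes fell in 3 of 29 and rose in none (median -0.19). The potassium channel Kcnj11 fell by 0.54, the calcium-binding protein Hrc of the sarcoplasmic reticulum fell by 0.47 and calsequestrin, Casq2, fell by 0.31, with limma adjusted p-values from 0.00786 to 0.0248, while triadin, Trdn, differed by -0.39 with an adjusted p of 0.057 in limma. Camera's adjusted p was 1.5e-04 and fry's 0.0412, and the adjusted p was 0.28 with an estimated correlation. Of the 29 genes 6 fell when adjusted over the list alone. The LacZ arrays scored -0.058 to 0.19. The dim array, at 0.0085, and GATA-4 arrays 4 and 5, at -0.0040 and 0.028, lay within that range. GATA-4 arrays 2 and 3, at -0.37 and -0.21, lay below it. Without the dim array 9 genes fell.

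Ribosomal protein genes had small positive differences in all 30 measured members, and Rpl3 (1.18-fold) and Rpl41 (1.22-fold) rose, while Rpl14 and Rpl35 differed by 0.26 and 0.22 and did not pass. The median was 0.12, camera's adjusted p 3.41e-08 and fry's 0.0321, and the adjusted p was 0.28 with an estimated correlation. Of the 30 genes 10 rose when adjusted over the list alone. Another probe set of Rpl3 differed in the opposite direction, and Rpl41 missed the threshold in 5 of the 10 fits that left out an array. Under median centring the list median was 0.028 with a camera adjusted p of 0.206, and with median centring and no dim array it was -0.061 (adjusted p = 0.602, the highest among the alternatives, whose lowest was 9.34e-09). The dim array scored -0.013, and the other GATA-4 arrays 0.0072 to 0.15, and 9 members rose without it.

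Cardiac transcription factors and GATA-4 targets did not shift as lists. Of 21 cardiac transcription factors only Gata4 itself rose (median -0.13, camera adjusted p = 0.380), and of 26 GATA-4 target and hypertrophy genes none changed (median 0.024, camera adjusted p = 0.667), where limma gave 0 members also adjusted over the list alone. Without the dim array 1 cardiac transcription factor rose and 1 fell, and 1 gene of the target and hypertrophy list fell. Taken after the values were seen, the natriuretic peptide genes Nppa and Nppb, classic targets of GATA-4, had differences of 0.12 (SE 0.10) and 0.21 (SE 0.11), with limma adjusted p-values of 0.530 and 0.294. Cardiomyocyte markers had a median of -0.054 over 22 genes and a camera adjusted p of 0.0944, and the giant sarcomere protein gene Ttn fell by 0.27 (limma adjusted p = 0.00957). Camera called the cardiomyocyte list without LacZ array 1 (adjusted p = 0.0485), the dim array (0.0253) or GATA-4 array 4 (0.046), without GATA-4 arrays 4 and 5 (0.0227), in the signals as deposited (0.00122) and under median centring without the dim array (1.54e-07, the lowest among the alternatives, whose highest was 0.461). The dim array scored 0.057 on this list and the other GATA-4 arrays -0.0998 to -0.0057.

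Angiogenesis genes went both ways among 31 measured: Plaur (2.14-fold), Plau and Hmox1 rose and Apln and Vegfa fell, the last by 0.37 on the log2 scale (limma adjusted p = 0.0292), with a median of 0.052 and a camera adjusted p of 0.737. Among 22 paracrine growth factors, Mdk (1.78-fold) and Gdf15 rose and Vegfa and Bdnf fell, where Gdf15 was dim with LacZ (log2 signal 4.73) and its 2.74-fold is approximate. Their median of -0.14 and mean of 0.14 differed in sign, and camera, which gave an adjusted p of 0.736, went with the mean. In these lists all but Apln and Mdk were named after their values were seen. The endothelial protein Ecscr rose 1.33-fold as the single changed marker of 18 (median -0.064, mean 0.012, camera adjusted p = 0.774), and it missed the threshold in 7 of the 10 fits that left out an array. Without the dim array 1 endothelial marker rose and 4 fell. Adjusted over the list alone, 4 angiogenesis genes rose and 2 fell, and 6 paracrine genes rose and 3 fell. With the dim array left out, 5 angiogenesis genes rose and 5 fell, and 7 paracrine genes rose and 4 fell.

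Markers of other cell types had few changed members, and camera at its preset correlation passed none of these lists with all arrays. It passed erythroid markers without GATA-4 array 2 (adjusted p = 0.0488, in a range of 0.0488 to 0.455 over the alternatives) and mesothelial markers without GATA-4 arrays 4 and 5 (0.0173, in a range of 0.0173 to 0.991), and fry passed atrial markers (0.0469, in a range of 0.0469 to 0.915). The fibroblast proteoglycan gene Ogn fell by 0.41 (limma adjusted p = 0.0155), and Dpt fell too among 20 fibroblast markers (median -0.17, camera adjusted p = 0.516). Of these markers 4 rose and 4 fell when adjusted over the list alone, and 3 rose and 5 fell without the dim array. None of 17 smooth muscle and pericyte markers changed (median 0.040, camera adjusted p = 0.455), and the dim array scored 0.38 on them against -0.18 to 0.059 on the other GATA-4 arrays. Without the dim array 1 of them rose and 1 fell. Clu, a chaperone, rose 1.12-fold among 11 atrial markers (median -0.22, camera adjusted p = 0.455), and differed by -0.072 under median centring without the dim array. Krt18 rose and Gpm6a fell among 6 mesothelial and epicardial markers, whose median of -0.31 and mean of 0.39 differ in sign (camera adjusted p = 0.573). In small lists of 5 to 8 genes, Gpd1, an enzyme of glycerol synthesis, rose 1.72-fold (adipocyte, camera adjusted p = 0.738), Dbh, which makes noradrenaline, rose 1.74-fold (nerve and Schwann cell, 0.833), Gypc fell by 0.25 (erythroid, 0.176), and in skeletal muscle Myh1 and Casq1 fell while Mybpc2 rose (0.595, with a median of -0.21 and a mean of 0.072). With single arrays left out, Clu and Gypc missed the threshold in 8 of 10 fits and Dbh in 6. Dpt, Gpm6a, Casq1 and Mybpc2 were named after their values were seen.

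**Figure D3:**
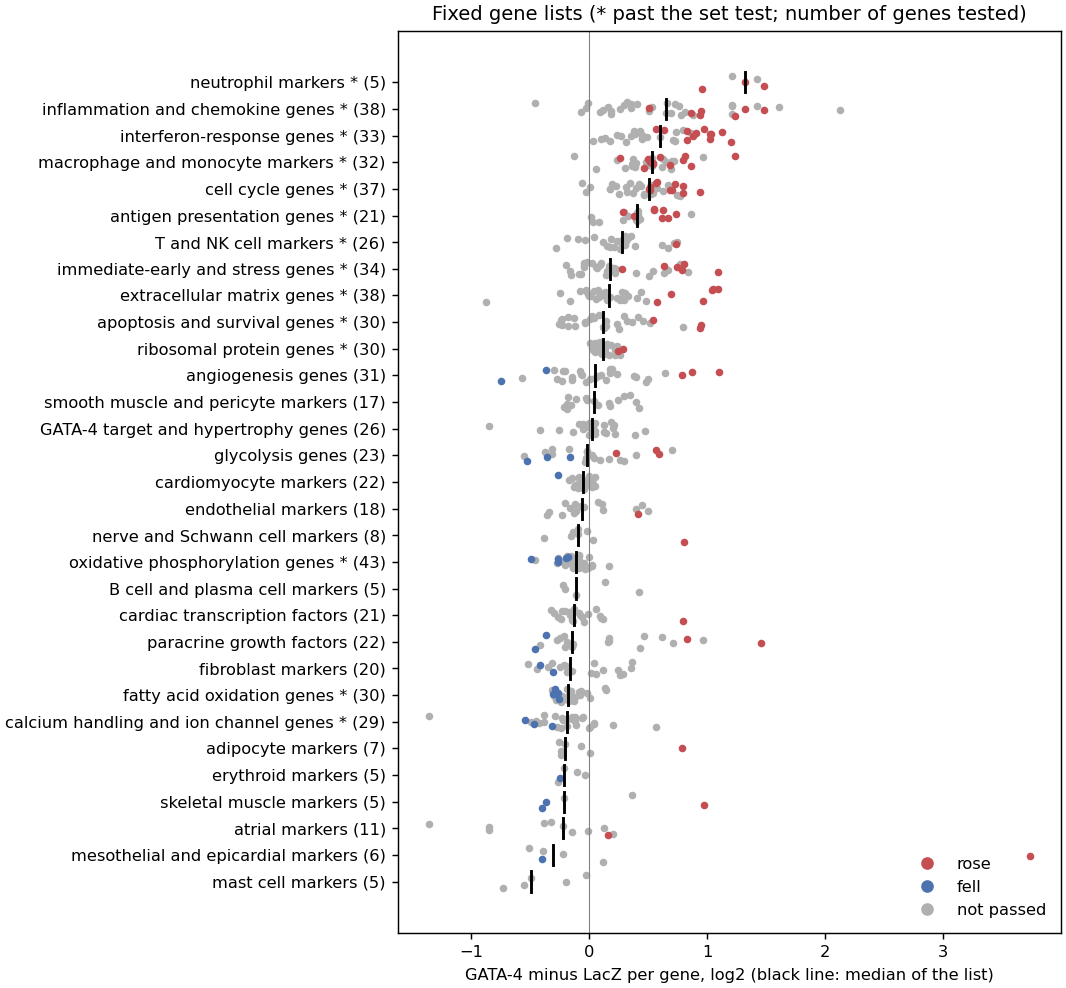
Each point is a gene of a fixed list at its log2 difference between GATA-4 and LacZ arrays, red where it rose, blue where it fell and grey where it did not pass, and a black line marks the list's median. Stars mark the 14 lists that camera passed at its preset correlation, from neutrophil markers with a median of 1.32 to calcium handling genes with -0.19.

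Camera passed 14 of the 31 lists, 11 upward and 3 downward. The estimated correlation in these lists ran from 0.138 for oxidative phosphorylation genes to 0.862 for neutrophil markers, above the preset 0.01. Camera's p-values at the preset value are therefore smaller than the spread between samples warrants. With an estimated correlation 0 passed, the smallest adjusted p was 0.28, and 4 lists had an unadjusted p under 0.05, while fry passed 12, of which 11 were among the 14.

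**Figure D4:**
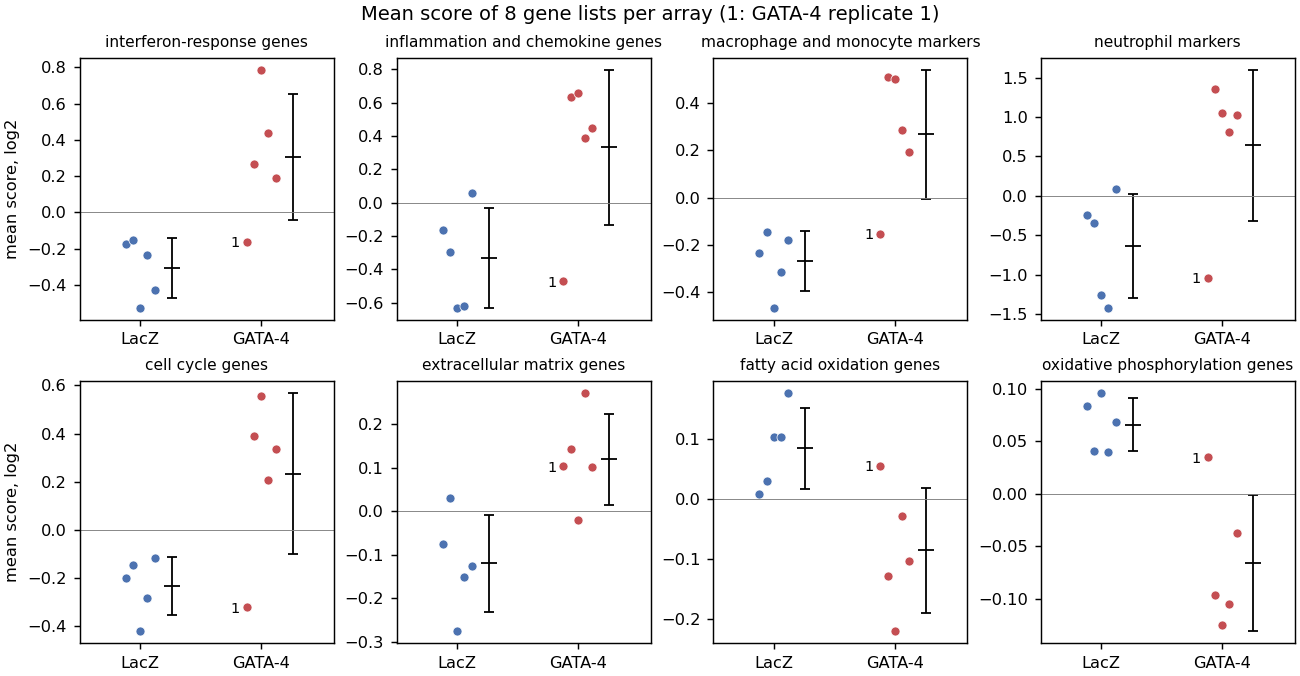
Points give each array's mean score, in log2 units, for 8 gene lists, with bars for the group mean ± SD and the dim array marked 1. That array lies with the LacZ arrays for interferon, inflammation, macrophage, neutrophil and cell cycle genes, and with the other GATA-4 arrays for matrix genes. It also lies within the LacZ range for fatty acid oxidation genes. For oxidative phosphorylation genes it lies nearer the LacZ arrays than the other GATA-4 arrays.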

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

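The tests of degraded RNA, less labelled target and the Gata4 level were chosen after the results were seen. The position and inflammation tests of the dim array are recorded as set beforehand. Both concern an array already seen to stand out, so they were not fixed before the data were examined. An array was picked out where its gap to the nearest of its group took an unusually large share of the group's range (Dixon's test). This happened in 13 of the 206 groups examined, and chance picks out about 1 in 20, which is 10.3 groups.

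The inflammation score of GATA-4 array 1, the dim array, was -0.47 against 0.39 to 0.66 on the other GATA-4 arrays, a gap of 0.761 of the range. Its neutrophil score was -1.04 against 0.81 to 1.35 (0.773). The neutrophil genes S100a8 (5.50 against 8.03 to 8.84, 0.756) and Csf3r (6.60 against 7.43 to 7.74, 0.729) and the gene C20h22orf15 (4.33 against 5.52 to 5.74, 0.839) were low on that array too.

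GATA-4 array 1 lay apart from the other 9 arrays. Its poly-A spikes, which go into the sample before labelling, read 1.31 lower, a difference of -1.31 from the median of the others on the log2 scale, so less labelled target may account for its dimness. Degraded RNA is argued against by its log2 3' to 5' ratio of 0.993, within the range of the other arrays. In normalized values the inflammation genes lay -1.004 from the other GATA-4 arrays, where 95% of random lists of like brightness lay between -0.263 and 0.139. This cannot decide on a loss that follows probe set brightness, since quantile normalization removes most of such a loss beforehand. The inflammation genes also vary together (estimated correlation 0.34), which genes drawn at random need not do. A wrong group label stays open by the position test, in which the array stood at 0.342 along the direction from LacZ (0) to the other GATA-4 arrays (1). That place lay beyond the LacZ arrays and nearer to them than to its group. The probe sets and their directions were chosen on the other 9 arrays, which widens the gap between the groups of those arrays. A place between the groups is therefore favoured whichever label is right. The array's normalized Gata4 level of 11.58, above all LacZ arrays, argues against that label being wrong, in a test added once the position had left it undecided. That argument rests on normalization, since its deposited Gata4 signal of 1741 lay within the 1432 to 2191 of the LacZ arrays. A weaker or later response in that sample was not tested.

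Of the remaining 8, 7 lay in the LacZ group, 3 of them on array 2 and 2 on array 5, and the cause was not tested. In LacZ arrays, Acsl1 was low on array 1 (12.57 against 12.69 to 12.70, a gap of 0.977 of the range), Cdkn1a was low on array 3 (10.32 against 10.75 to 10.82, 0.858), Gypc was low on array 2 (11.31 against 11.44 to 11.45, 0.878) and Ndufb10 was low on array 2 (12.24 against 12.35 to 12.39, 0.733). Cd14 was high on LacZ array 5 (9.64 against 9.15 to 9.28, 0.743), as was Trdn (10.54 against 10.46 to 10.48, 0.723). The log2 trimmed mean signal was high on LacZ array 2 (8.30 against 7.97 to 8.05, 0.762), and Gpd1 was high on GATA-4 array 3 (11.48 against 11.12 to 11.15, 0.918).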

How the results depend on the processing

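The settings without GATA-4 arrays 4 and 5 and with median centring without the dim array were chosen after seeing the data. Against the 988 changed probe sets (566 higher, 422 lower), the signals as deposited gave 9, 9 and 0, no filter gave 619 with 227 lower, no intensity trend 539 (358 and 181), array weights 2890 (1435 and 1455), GATA-4 arrays 4 and 5 left out 201 (139 and 62), and median centring without the dim array 3154 (1215 and 1939). Leaving out single arrays gave 174 to 2849 changed, 142 to 1464 higher and 32 to 1385 lower, with the lowest counts without LacZ array 3 and the highest without the dim array, and the count also moved by more than 1.5 times without LacZ arrays 1, 4 and 5 (384, 391 and 323) and GATA-4 arrays 3, 4 and 5 (341, 558 and 539). The exploratory count of 575 was 147 as deposited, 362 with the stricter filter, which tests fewer probe sets, 901 with median centring without the dim array, and 448 to 882 with single arrays left out. As deposited, differences in brightness between arrays stay in the values, and beyond this and the fewer arrays or probe sets of some settings the cause was not tested. All changed probe sets that a setting tested kept their direction, except 1 of 986 under median centring without the dim array. Gata4 passed under every setting but the signals as deposited (0.70, adjusted p = 0.993), with 0.75 to 0.84 when single arrays were left out and adjusted p-values from 1.03e-04 to 0.993 over all settings. Of the 84 other named genes followed, 11 lost their call under median centring, 69 as deposited and 43 without LacZ array 3, and Clu alone changed sign (-0.072, median centring without the dim array). That setting also turned the median of the ribosomal list to -0.061. Lists past camera numbered 13 to 16 except with an estimated correlation (0), and 13 to 15 with single arrays left out. The 3' to 5' difference of -0.0017 ranged from -0.068 to 0.088 with single arrays left out, and was -0.194 against the middle probe sets (exact p = 0.0476). Of 100 splits of the arrays into 5 and 5, 1, the real one, gave 988 changed probe sets, the highest other being 17. At the exploratory threshold 1, the real one again, gave 575, the highest other being 472. A share of 1 in 100 is the smallest these splits can give, so they make chance unlikely without excluding it. The 3 highest of these other splits, with 472, 469 and 407, each set the dim array beside 4 LacZ arrays and so kept the other 4 GATA-4 arrays together. No paired analysis was possible because the numbers only name arrays within a group and pair no samples. Dim probe sets, near background, limit what could be seen, and the 5 arrays in a group limit precision.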

Other observations

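The gene families and their members in this paragraph and the next, and the tests weighed after them, were chosen after the results were seen. Only the test of the 3' to 5' ratio is recorded as set beforehand, though it concerns a rise already seen. Tubulin genes rose in 4 of 11 measured and fell in none: Tubb3, a tubulin typical of neurons, 2.71-fold, Tubb6 2.14-fold, Tubb5 1.44-fold and Tubb4b 1.17-fold, with limma adjusted p-values from 0.00242 to 0.044. Among 12 cathepsins, proteases of the lysosome, 11 had positive differences (Ctsh turned negative under median centring) and Ctsz (1.72-fold), Ctsa (1.27-fold) and Ctsb (1.18-fold) rose. The protein disulfide isomerases Pdia6 (1.27-fold) and Pdia3 (1.21-fold), which fold proteins in the endoplasmic reticulum, rose among 6. The calcium-binding proteins S100a6 (1.47-fold) and S100a11 (1.26-fold) rose among 10 of their family. Of 7 subunits of the actin-branching Arp2/3 complex Arpc1b rose 1.59-fold, and all 7 differences were positive except that Arpc1a and Arpc2 turned negative under median centring. The genes named here as rising had positive differences under every scaling tried. Also looked at were keratins (1 of 5 rose), complement genes (1 of 12), translation initiation factors (1 of 49) and aldolases (1 of 2). Over all genes tested 397 of 10688 rose, and no family was tested against that share.

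Of 36 proteasome subunits, those that rose were Psmb8 and Psmb9, which replace standard subunits in cells exposed to interferon. Psmb10 differed by 0.43 and narrowly missed the threshold (limma adjusted p = 0.0506), and by 0.40 under median centring. The family's median was 0.046, and many of its other members, such as Psma6 and Psmb1, turned negative under median centring. Of 32 potassium channel genes Kcnj11 and Kcnk2 fell and Kcnn4, a calcium-activated channel also found in immune cells, rose 2.02-fold. The third measured member of the Reg family, Reg3b, was already bright with LacZ, at a log2 signal of 12.51, and read 13.16 with GATA-4, a difference of 0.65 that did not pass limma (adjusted p = 0.1505).

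Of the immune markers 12 of 32 for macrophages, 3 of 5 for neutrophils and 1 of 26 for T and NK cells rose, none for B or mast cells changed, and no list passed camera with an estimated correlation. A lower share of cardiomyocyte RNA as the whole cause of the macrophage rise is argued against, because it would raise markers of all other cell types alike, and the macrophage score rose by 0.538 more than the mean score of endothelial, fibroblast and smooth muscle markers (exact p = 0.0397). RNA quality stays open: the difference was 0.395 after the 3' to middle ratio was regressed out (exact p = 0.0556), and the 0.538 left after regressing out the 3' to 5' ratio (exact p = 0.0159) decides nothing, since that ratio did not differ between groups. Nor does the 0.642 without the dim array (exact p = 0.00794, the smallest that 4 and 5 arrays allow), which had the lowest macrophage score of its group, and neutrophil markers were not weighed apart; more immune cells or more expression per cell may underlie the rise but were not separated. Of the 32 macrophage markers 2 are in another list, 26 lay above the median signal of tested probe sets on the LacZ arrays, and the 3 brightest over all arrays, Lyz2, Gpnmb and Fcer1g, read 12.96, 12.38 and 12.49 with GATA-4 against 12.70, 12.14 and 11.97 with LacZ, where Gpnmb did not pass.

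Of fatty acid oxidation genes 6 of 30 fell and of oxidative phosphorylation genes 5 of 43. Over these 73 genes the score fell by 0.147, and it fell by 0.0859 more than that of 17 structural cardiomyocyte genes, -0.0859 with an exact p of 0.00794, the smallest the 252 assignments allow. Under median centring that difference was -0.103 (exact p = 0.103), and -0.0505 without the dim array (exact p = 0.167), a condition added after the first value was seen, so a lower share of cardiomyocyte RNA and a metabolic change cannot be told apart. Under median centring the metabolic score fell further but with a wider spread, -0.228 with an exact p of 0.0873 (-0.329 without the dim array, exact p = 0.0159), so the exact test leaves normalization open although the values do not point to it. Camera passed the oxidation and phosphorylation lists under median centring (adjusted p = 1.17e-05 and 8.46e-05) and as deposited (7.51e-09 and 3.06e-10), in ranges of 6.59e-10 to 0.28 and 1.01e-14 to 0.28 over the alternatives, and the fall remains a hypothesis that could rest on either cause.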
